A study of Rattus norvegicus with 24 samples.

How the data were processed

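Gene expression in rat kidney was measured on 24 two-colour cDNA arrays, each hybridised with 2 RNAs. Per the labels, the arrays compare high salt (HS) with low salt (LS) after 2 weeks in strain 13, the same diets in strain SS, and strain 13 with strain SS on LS and on HS. The abbreviations are read as high and low salt from what is known of the study, as is the fact that strain 13 is the SS rat carrying chromosome 13 of another strain. The series title places the work in the renal medulla, while the labels say kidney. Each of the 4 comparisons holds 6 arrays, made of 3 replicates with a forward and a dye-swap array each. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Of the 6 arrays of the SS diet comparison, 5 have titles that give no strain, and the remaining title opens like those of strain 13 while its channel text names SS on both diets. That array was placed by its channel text and left out as an alternative. In the strain 13 diet group, 1 title gives no replicate number.

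The deposited values are log ratios of the 2 channels, with the log base not given in the sources used here. The design had assumed log base 2, so values are given as log ratios with no fold. Background correction, spot filtering and normalization are not given in the sources used here. From the values, every array had a mean within 0.0049 of 0 and a median within 0.04 of 0, and was used as deposited. The table lists 3502 probe IDs, of which 1561 held a value on at least 1 array. Each of 1487 clones is listed at 2 probe IDs, values stood at the first for 1338 clones, and 0 clones had values at both. Between 726 and 1402 probes held a value per array (median 1202.5), 548 on all arrays. Intensities are not used here, so the number of arrays limits the precision.

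Probes were named through the platform annotation, updated by gene identifier with the RefSeq table of assembly GRCr8, which was used only for names and chromosome membership. Of the 1561 probes with values, 1311 had 1 updated symbol, 5 a platform symbol only, 22 several symbols and 223 none. As a check of the names, the median pairwise correlation was 0.74 for 4 collagen probes, 0.124 for 31 cytosolic ribosomal protein probes and -0.0076 over 1221 probes.

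The sign of the ratios was examined from the arrays. A dye effect is common to all comparisons, and between pairs of different comparisons the difference of forward and dye-swap arrays had a median correlation of 0.47 and their sum 0.24. The deposited values were therefore taken as already turned to one channel order. If all 4 comparisons run in the direction of the labelled channels, the diet ratio of strain 13 minus that of SS should equal the strain ratio on HS minus that on LS. Across probes these correlated with r = 0.65 over the replicate means (genes are not independent replicates), while turning 1 diet group, 1 strain group or one of each gave -0.23, 0.17 and 0.29. Over the 548 probes on all arrays the correlation was 0.77 for the sum of the orientations and 0.22 for their difference. The relative signs are taken from this, and a turn of all signs at once stays open. The direction HS over LS and 13 over SS is called likely, because the 13 titles that name the channels put strain 13 or HS in channel 1, but only 1 of these is of the 12 diet arrays. All 24 titles, those of strain arrays included, open with LS before HS, the opposite order. Counts of changed genes do not depend on it.

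The arrays of each replicate were averaged, giving 12 RNA pairs, and a probe was tested where at least 2 of the 3 replicates had a value. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) fitted 4 group means to all 12 pairs, with each mean tested against 0 (two-sided) and Benjamini-Hochberg adjustment at 0.05. The difference of the diet change between strains was the mean of its diet-array and strain-array estimates, in the same fit. These estimates may share RNAs, and the fit treats them as independent. The channel names give such sharing only for SS in replicate 3. In the data, same-numbered deviations of the SS diet and HS strain comparisons correlated at -0.67, -0.59 and -0.29 across genes. A shared SS RNA on HS would make them negative. Those of the SS diet and LS strain comparisons correlated at 0.40 in replicate 3, the sign that a shared SS RNA on LS predicts. In replicates 1 and 2, where no names give sharing, they correlated at -0.04 and -0.25. The other comparisons showed no such clear sign. On data simulated without effects and with shared RNAs for 20 datasets, 8.68% of the interaction p-values were below 0.05, against 5.30% for a fit to the 3 per-replicate values alone and 4.33% to 5.87% for the other comparisons. On data simulated with effects in SS on HS only, 58.1% of probes with a true log ratio of 0.3 and 87.3% of those with 0.5 were called in the SS diet comparison. Of the probes without an effect, 186 of 22200 (0.84%) were called there and 369 of 19280 (1.91%) for the interaction. Effects were given only to probes with a value in all RNA pairs, 50 each at 0.3, 0.5, 0.8 and 1 per dataset. So many effects ease the adjustment, so the shares called may be too high for the real data.

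Gene lists and cell type markers were fixed before the data were examined, as were the design, the named-gene rule and most alternatives. The lists cover sodium, potassium and water transport, steroid and vasoactive hormones, nitric oxide and eicosanoids, redox defence, osmolytes and heat shock proteins, extracellular matrix, immune genes, mitochondrial energy metabolism, and markers of proximal tubule and cortex, blood, smooth muscle, endothelium, lymphoid and myeloid cells and fat. Lists with at least 5 measured genes that had a value in all pairs were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, adjusted over lists within a comparison. There were 23 symbols on more than 1 list. Genes on chromosome 13 were set against the rest with Fisher's exact test (two-sided). Named genes are the 10 highest and 10 lowest called genes whose replicates share a sign, the 10 with the lowest p where fewer passed, the lowest-p pair of members of each list, and Hsd11b1. A further gene of the rule is not reported here.

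Alternatives covered array centring and spread, missing values, the fit, the dye orientation, the threshold, the loop of comparisons and each replicate left out. A threshold of 3 for extreme values removed 0 probes and tests nothing. A proximal tubule covariate and the leaving out of a sparse array were added after seeing the data.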

Results

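Transcript levels in kidney of salt-sensitive (SS) rats and of strain 13, an SS rat with a substituted chromosome 13, were compared on low salt (LS) and high salt (HS) after 2 weeks. Each of the 4 comparisons had 3 replicates, each hybridised on 2 arrays with the dyes exchanged. Arrays held between 726 and 1402 probes with a value. All ratios are deposited log ratios of unstated base, given as mean ± SD with n = 3 unless stated. The direction HS over LS and 13 over SS is likely, from the channels named in 13 titles and the closure of the 4 comparisons, although only 1 of these titles is of a diet array and all titles open with LS before HS; the alternative is that every sign turns at once.

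The first comparison asks which transcripts differ between HS and LS in the salt-sensitive SS strain. Some genes of the extracellular matrix were higher on HS. Col1a1 and Col3a1, which encode fibrillar collagens, had log ratios of 0.95 ± 0.43 and 0.82 ± 0.32 (limma adjusted p = 0.0105 for both). Timp1, an inhibitor of matrix metalloproteinases, had 0.91 ± 0.26 and Col2a1 0.66 ± 0.14. Of the 28 measured members of the matrix list, 6 rose, 0 fell and 22 did not pass the test, and 9 rose when adjusted over the list alone. The remaining called members were Spp1, the matrix protein osteopontin, at 0.40 and Vim, the mesenchymal filament vimentin, at 0.37. The matrix list had a median of 0.21. It shifted up by camera at the preset correlation of 0.01 (adjusted p = 7.08e-06) and by fry (adjusted p = 0.0104). It did not pass by camera with its estimated correlation of 0.24 (adjusted p = 0.242).

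Of the 5 measured smooth and skeletal muscle markers 2 passed in SS and 3 did not, with 5 above 0 (median 0.49) and no list test. Tagln, an actin-binding protein of smooth muscle, had 0.70 ± 0.35 and Tnnt2, cardiac troponin T, 0.57 ± 0.12, while Acta2, smooth muscle actin, had 0.09 ± 0.12. Of 7 lymphoid and myeloid markers 0 passed and 6 were above 0 (median 0.22). Clu, a secreted chaperone, rose by 0.71 ± 0.38, Mgp, an inhibitor of calcification, by 0.61 ± 0.21, and the kinase genes Csnk2b and Prkcb by 0.72 ± 0.29 and 0.61 ± 0.05. Galr2, a galanin receptor, had 0.68 ± 0.09. Among 24 redox genes, Mt2A (a metallothionein) rose by 0.47 ± 0.13 and Cyba (a subunit of NADPH oxidase) by 0.38 ± 0.20, while Aldh1a1 had -0.27. Of 19 immune genes 1 rose, Cp (ceruloplasmin, 0.34 ± 0.13), and 6 when adjusted over the list alone. The immune list had a camera adjusted p = 0.00288, a fry adjusted p = 0.0193, and an adjusted p = 0.242 with an estimated correlation. None of the endothelial, fat or blood markers measured passed.

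Lower on HS in SS were 13 genes. Dnase1 had -0.52 ± 0.09, Slc16a7, a monocarboxylate transporter, -0.48 ± 0.25, and Acsl1, which activates long-chain fatty acids, -0.39 ± 0.17. Got1 and Bcat2, amino acid transaminases, had -0.33 ± 0.06 and -0.31 ± 0.05, Gcgr, the glucagon receptor, -0.43 ± 0.19, and Isyna1, which makes inositol, -0.46 ± 0.16. Vegfa had -0.41 ± 0.16 and Tmbim6 -0.55 ± 0.24. Of the 11 measured transport genes 0 passed, with a median of -0.11. Their list had a camera adjusted p = 0.0375, a fry adjusted p = 0.0104, and an adjusted p = 0.242 with an estimated correlation. Slc12a1, the loop diuretic-sensitive cotransporter, had -0.23 ± 0.04 and Umod -0.25 ± 0.03, neither past the threshold.

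In total, 37 of 1310 probes tested in SS passed (24 higher, 13 lower), and 255 had an unadjusted p below 0.05. The count rests on replicates 2 and 3: it was 57 without replicate 1 and 0 without either of the others, and 0 when these 3 values were fitted alone. Without the array whose title opens like those of strain 13 it was 60 (40 higher, 20 lower). Replicate 1 correlated with replicates 2 and 3 across genes at 0.19 and 0.02, against 0.56 between those. The mean of 11 proximal tubule markers was 0.24 in replicate 1 and -0.33 in replicates 2 and 3, where Col1a1 had 0.46, 1.245 and 1.135. The proximal tubule list of 15 genes had 13 below 0 (median -0.17). Its camera adjusted p was 0.0381 at the preset correlation and 0.588 with an estimated correlation, and its fry adjusted p was 0.25. Vegfa was 0.14 on the dye-swap arrays alone, where a dye effect does not cancel.

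**Figure D1:**
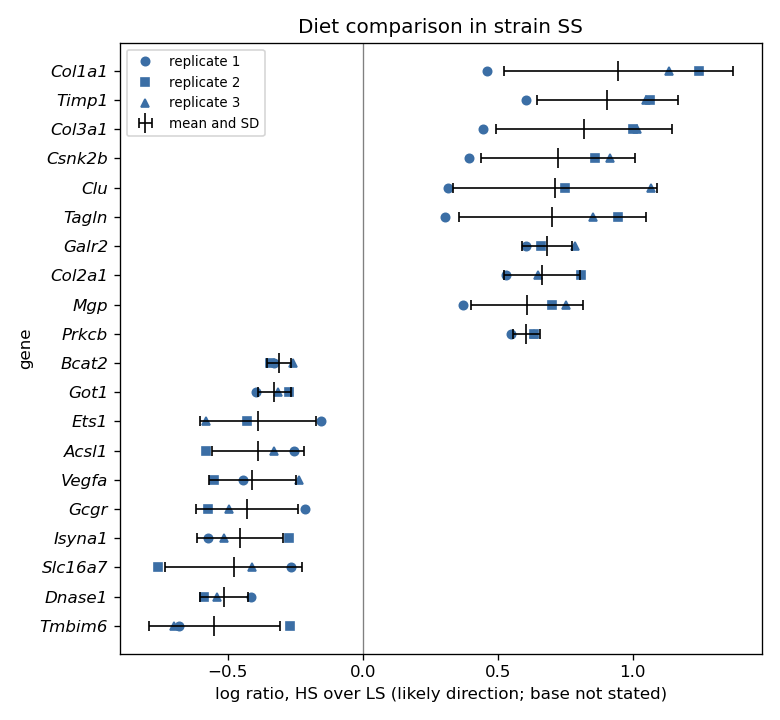
Log ratio (HS over LS, likely direction, base not stated; horizontal axis) of the 10 highest and 10 lowest called genes of strain SS, 1 gene per line, with each of 3 replicates as a point and the mean and SD as bars. Col1a1 is the highest at 0.95 and Tmbim6 the lowest at -0.55.

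The same diet comparison in strain 13 called 0 of 1287 probes (limma; lowest adjusted p = 0.324). At an unadjusted p below 0.05 there were 119 probes, and an ordinary per-probe test called 1. Among the genes with the lowest p, Amacr, a peroxisomal racemase, had -0.72 ± 0.24, Akr7a3, an aldehyde reductase, -0.73 ± 0.36, and Pcsk1n -0.45 ± 0.24. Spink1l had 0.36 ± 0.02 and Cd53, a leukocyte membrane protein, 0.37 ± 0.28. Col3a1 had 0.34 ± 0.14 (adjusted p = 0.417). The matrix list had a median of 0.13 (camera adjusted p = 0.0011), and the proximal tubule list of 14 genes a median of -0.35 (camera adjusted p = 2.21e-05). Both had an adjusted p = 0.422 with an estimated correlation and a fry adjusted p = 0.25. Gatm, which makes the creatine precursor, had -0.56 ± 0.31 and Cyp2e1, a cytochrome P450, -0.40 ± 0.12.

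On LS the comparison of strains called 0 of 1229 probes (limma; lowest adjusted p = 0.0904), with 268 below an unadjusted p of 0.05 and 1 called by the ordinary per-probe test. At an adjusted p of 0.1 there were 48. Among the 10 genes with the lowest p, Hsd17b4, of peroxisomal oxidation, had -0.39 ± 0.10, Acadl, an acyl-CoA dehydrogenase, -0.33 ± 0.11 and Cycs, cytochrome c, -0.44 ± 0.19. Of the 42 mitochondrial genes 0 passed, with 22 above and 20 below 0 (median 0.01, camera adjusted p = 0.896). Ralb, a small GTPase, had 0.34 ± 0.13 and Nr2f6 0.35 ± 0.13. Fxyd4 had 0.32 ± 0.14 and Aqp3, a water channel, 0.23 ± 0.08 (adjusted p = 0.0904 for both). Hsd11b1, which regenerates active glucocorticoid, had -0.27 ± 0.08 (adjusted p = 0.116), and was -0.20 ± 0.14 on HS. The proximal tubule list had a median of -0.16 (camera adjusted p = 0.0113, fry adjusted p = 0.497, and adjusted p = 0.934 with an estimated correlation). Scaling every array to the same spread called 23 probes.

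On HS, 2 of 14 proximal tubule and cortex markers were lower in strain 13 than in SS, Gatm (-1.03 ± 0.55) and Cyp2e1 (-0.67 ± 0.39), 1 was higher (Egf, made in the distal tubule, 0.29) and 11 did not pass. The list median was -0.41 (camera adjusted p = 0.00264, fry adjusted p = 0.0857, and adjusted p = 0.3 with an estimated correlation). Outside this list, Cyp2c23, an arachidonic acid epoxygenase, had -1.19 ± 0.63, Kmo and Aadat, enzymes of kynurenine metabolism, -0.74 ± 0.48 and -0.66 ± 0.55, and Amacr -0.60 ± 0.39. Lyz2, the lysozyme of myeloid cells, was the lowest gene at -1.51 ± 0.83, while 0 of the 6 other lymphoid and myeloid markers passed. The 11 proximal tubule markers with a value in every RNA pair averaged -0.81, -0.09 and -0.45 in replicates 1 to 3.

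**Figure D2:**
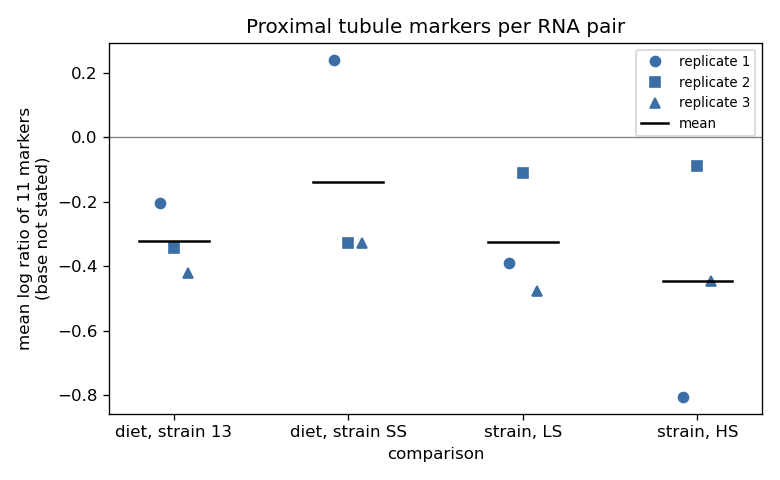
Mean log ratio of 11 proximal tubule markers (vertical axis, base not stated) in each of the 12 RNA pairs by comparison, with 1 point per replicate and a line at the mean of the 3. The lowest point is -0.81, replicate 1 of the strain comparison on HS, and the highest 0.24, replicate 1 of the diet comparison in SS.

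Several genes of salt and water transport were higher in strain 13 on HS. Fxyd4, a regulator of the sodium pump, had 0.50 ± 0.11, Aqp3 0.35 ± 0.07, Scnn1a, a subunit of the epithelial sodium channel, 0.38 and Atp1b1, a sodium pump subunit, 0.25. Thus 4 of the 11 transport genes rose and 0 fell (camera adjusted p = 0.00264, fry adjusted p = 0.000141, and adjusted p = 0.0669 with an estimated correlation). Acsl1 and Bcat2 had 0.51 ± 0.05 and 0.52 ± 0.09, Gcgr 0.52 ± 0.15, Dnase1 0.71 ± 0.27, and Ldhb, a lactate dehydrogenase, 0.39 ± 0.13. Of 41 mitochondrial genes 2 rose. Among matrix genes 3 of 28 fell (Spp1 -0.37, Vim -0.34 and Col2a1 -0.42) and Pdgfa rose (0.34 ± 0.07). Of 7 smooth and skeletal muscle markers 1 fell (Tnnt2, -0.48 ± 0.04) and 6 were below 0 (median -0.25). Clu had -0.60 ± 0.07 and Csnk2b -0.55 ± 0.13. Kdr, a receptor of VEGF on endothelium, had 0.32 ± 0.12, and C3 -0.37 ± 0.07. Igfbp5 had 0.60 ± 0.45, and -0.02 on forward arrays alone, where a dye effect does not cancel.

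In total 81 of 1350 probes passed (49 higher, 32 lower), and 312 had an unadjusted p below 0.05. The count was 0 without replicate 1, 12 without replicate 2, 19 without replicate 3 (17 higher, 2 lower), 0 when the 3 values were fitted alone, 40 with the replicate number as a block (30 higher, 10 lower, 39 of them among the 81), and 13 (10 higher, 3 lower) with arrays scaled to equal spread. With the proximal tubule mean as a covariate, chosen after seeing the data, it was 21 with most of them lower (7 higher, 14 lower), of which 11 were among the 81.

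**Figure D3:**
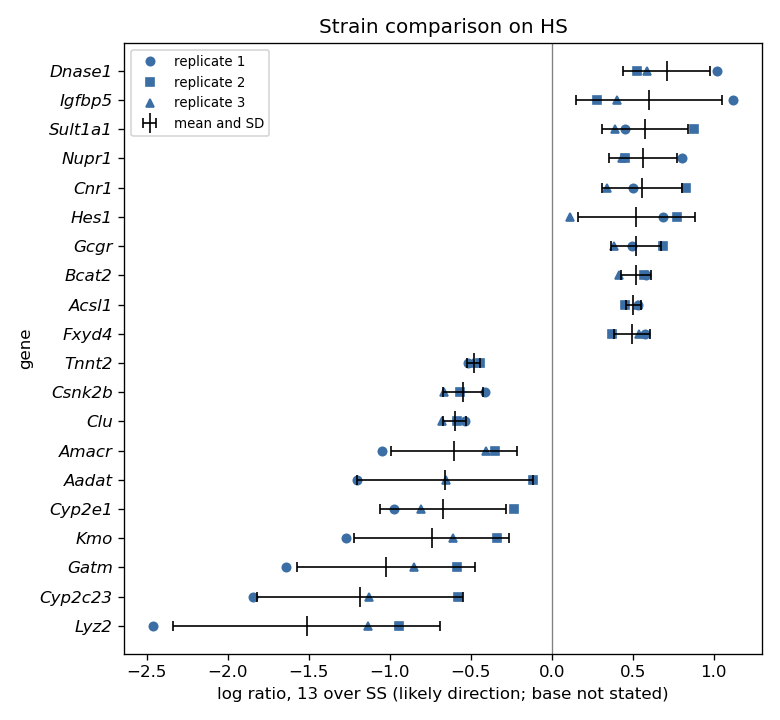
Log ratio (13 over SS, likely direction, base not stated; horizontal axis) of the 10 highest and 10 lowest called genes on HS, 1 gene per line, with each of 3 replicates as a point and the mean and SD as bars. Replicate 1 is the lowest for Lyz2, Cyp2c23 and Gatm.

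Between the SS diet comparison and the strain comparison on HS, 17 probes were called in both, all with opposite signs, where independent lists would share 2.31. Both comparisons use SS RNA on HS, by the channel names the same extract in replicate 3, with no names given for the diet arrays of the others. SS on HS stands on opposite sides of both ratios, so a shared RNA or a change in that condition alone gives opposite signs. In 20 datasets simulated without effects the highest number shared was 0. Each comparison called a mean of only 0.05 probes there, and real effects were left out, so this cannot decide the question. Part of the excess may come from the shared RNA.

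Genes on chromosome 13 made up 8 of the 68 genes called on HS with a known chromosome. Of the 32 tested on that chromosome 25% were called, against 5.43% elsewhere (odds ratio 5.79, Fisher's exact test, two-sided, p = 0.000357). These were Ctse, Tor1aip1, Mtarc2, Ralb and Atp1b1, higher, and Kmo, Tnnt2 and Apcs, lower. Some are named because they were called, after their values were seen. Ctse and Apcs had no value in replicate 1 (n = 2), and Apcs had -0.46 in both others. At an unadjusted p of 0.01, 8 of 32 were called on HS (odds ratio 3.31, Fisher's exact test p = 0.00814) and 2 of 29 on LS, which is 6.90% against 7.94% elsewhere. On HS it was 0 of 11 called genes without replicate 2, 1 of 16 without replicate 3 (Fisher's exact test p = 0.351) and 2 of 20 with the covariate (p = 0.106).

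The diet change differed between the strains for 5 of 1164 probes. The interaction (diet change in 13 minus that in SS) was 0.45 ± 0.10 for Acsl1, 0.38 ± 0.02 for Pcsk6, a proprotein convertase, and 0.56 ± 0.17 for Slc16a7. It was -0.68 ± 0.08 for Csnk2b and -0.46 ± 0.11 for Tnnt2 (limma adjusted p from 0.0353 to 0.04999). Csnk2b rose by 0.72 on HS in SS and had 0.07 in strain 13, and Acsl1 had -0.39 and 0.04. In replicate 3 the strain arrays of both diets share a text in their titles that may mark a batch. The strain-array estimate within it was 0.40 for Pcsk6, -0.49 for Tnnt2 and of the same sign as the whole for the other 3. These values are among those by which the 5 genes were called, so they cannot decide whether a batch plays a part. In replicates 1 and 2 this text differs between the LS and HS strain arrays. There the strain-array estimate cannot be told apart from such a batch. The matrix genes Col1a1 (-0.67, adjusted p = 0.0593) and Timp1 (-0.62, adjusted p = 0.0569) did not pass. The matrix, immune, mitochondrial and transport lists each had a camera adjusted p = 0.00907, and adjusted p = 0.405, 0.311, 0.311 and 0.112 with an estimated correlation. In the same order their fry adjusted p was 0.15, 0.0864, 0.0372 and 0.00145. The mitochondrial and transport lists thus passed by fry, and the matrix and immune lists did not. The 4 smooth and skeletal muscle markers with a value, Tnnt2 among them, were all below 0 (median -0.30). The fit treats its estimates as independent although they may share RNAs. In data simulated with shared RNAs and no effects, 8.68% of the interaction p-values were below 0.05. With simulated effects in SS on HS, 1.91% of the probes without an effect were called for the interaction. The p-values of the 5 genes may thus be too low. The 3 per-replicate values alone called 0. The count was 8 with the replicate number as a block (4 of the 5 kept), 10 without replicate 1 and 0 without replicate 2 or 3. It was 0 with equal spread, 23 for probes without missing values and, as alternatives added after seeing the data, 2 without the LS strain array that held the fewest values and 44 with the covariate.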

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

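The tests of the proximal tubule share, of a single replicate, of dye bias, of muscle markers, of the matrix genes other than Col1a1 and Col3a1, of the conflicting label and of chromosome 13 alleles were chosen after the result was seen, as were the covariate and the sparse-array alternative.

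On LS, the forward array of replicate 1 of the strain comparison held 726 values, against 1099 on the next lowest of the group of 6, and its SD of 0.474 stood apart from the next at 0.318. Of the 12 group sets examined, chance would flag about 1 in 20. Without it the strain count on LS stayed 0, and the interaction count was 2. The text in its title that may mark a batch is shared with no other strain array, its dye swap included.

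The diet change differed between strains by test for Acsl1 (0.45), Pcsk6 (0.38), Slc16a7 (0.56), Csnk2b (-0.68) and Tnnt2 (-0.46). This test gave too many low p-values in data simulated with shared RNAs (8.68% below 0.05 without effects).

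Of 14 proximal tubule and cortex markers 2 passed as lower in strain 13 on HS and 1 as higher, and the list had an adjusted p = 0.3 with an estimated correlation. All of the 11 proximal tubule markers with a value in every RNA pair (100%) lay below 0, with a median pairwise correlation of 0.61 over the 12 pairs. The ratios ran from -1.03 for Gatm to -0.05 for Mep1b, with Kap at -0.42 and Lrp2 at -0.44. This is what a larger share of proximal tubule in the SS tissue would show, and a strain difference in these genes stays open beside it, since the outer medulla itself holds proximal straight tubule. A dye effect of a probe cancels where both orientations were measured, as in 16 of 18 RNA pairs of the 6 called genes named. The 11 markers, not chosen by their calls, had a median of -0.40 on forward arrays (-0.64 to -0.16 with 2 SE over the markers) and -0.42 on dye-swap arrays, where a dye effect would give opposite signs. This argues against dye bias for the markers if the values are turned as taken. The SE over the markers, here and below, takes them as independent although they vary together. It does not measure the spread between replicates. Replicate 1 had a marker median of -0.82, and without it the median was -0.23 rather than -0.42, past the bound of -0.2 set for it but within 1 SE of the markers (-0.29 to -0.16), a margin added after the value was seen, so it does not exclude that 1 replicate carries most of it. If same-numbered arrays share the SS RNA on HS, that RNA is also on the diet pair where the markers averaged 0.24, so uneven dissection could account for part of the pattern. With the marker mean as a covariate, genes not among the markers moved towards 0, Cyp2c23 from -1.19 to -0.56 (SE 0.22 and 0.19), Kmo from -0.74 to -0.21 (SE 0.19 and 0.16) and Aadat from -0.66 to -0.11 (SE 0.17 and 0.11), and were no longer called. The strain count fell from 81 to 21 with 10 new calls, but over the 79 called probes that are not markers the median size went only from 0.39 to 0.36 while the median SE went from 0.08 to 0.11, so the lower count does not show that the other calls stem from proximal tubule. The lower marker ratios are not particular to HS. On LS the 11 markers also lay below 0 between strains, from -0.72 for Gatm to -0.02 for Khk. In both diet comparisons all but Fbp1 (0.01 in strain 13 and 0.15 in SS) lay below 0. For the interaction the proximal tubule and cortex list had a camera adjusted p = 0.391.

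Of 28 matrix genes 6 passed as higher on HS in SS, and the list had an adjusted p = 0.242 with an estimated correlation. Both dye orientations were measured in 17 of 18 RNA pairs of the 6 called genes. The whole list was not chosen by its calls. It had a median of 0.22 on forward arrays (0.07 to 0.37 with 2 SE over its genes) and 0.28 on dye-swap arrays. This argues against dye bias in the same way and with the same limit of the SE. The median of the called genes was 0.74 both with and without the array whose label names both strains (0.739 without). If more interstitial cells with unchanged genes per cell were the cause, decorin and biglycan should rise with the collagens, but their mean was 0.23 (95% interval 0.04 to 0.42), below the lower ends for Col1a1 (0.61) and Col3a1 (0.57). This holds for these genes unless much of the decorin and biglycan signal comes from other cells. Col1a1 and Col3a1 are also among the highest called genes of this comparison, so selection may have raised their ratios. Decorin and biglycan were not called, so the difference may be overstated. Of the other called matrix genes, 2 of 4 (Timp1 and Col2a1) had a lower end above 0.42, while Spp1 and Vim did not. More smooth muscle and pericytes stay open: 5 of 5 muscle markers were above 0 (median 0.49), although Acta2 (0.09, upper end 0.26) lay below the lower ends for the collagens. Lymphoid and myeloid markers were above 0 in 6 of 7 (median 0.22). An effect of the diet on the matrix genes cannot be told apart from such a change of cells.

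Chromosome 13 genes made up 8 of 68 called on HS, but 0 of 11 without replicate 2, 1 of 16 without replicate 3 (Fisher's exact test p = 0.351) and 2 of 20 with the covariate (p = 0.106), where few called genes are left to show an excess. On LS, 6 of the 8 had the sign they had on HS, with a median 0.444 of that on HS, so allele differences present on both diets cannot be told apart from other causes with 8 genes; for called genes on other known chromosomes it was 0.362, with 45 of 58 of the same sign. A larger spread on LS is argued against, with a ratio of the SDs of 1.02.

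Turning the sign of replicates gives 4 splits per comparison, too few for a share under 0.05. The real counts were 37 in SS, 81 between strains on HS and 5 for the interaction, with 0 as the highest of the other splits and 1 split as large in each, the real one. In strain 13 and on LS the real count was 0, with 1 and 0 as the highest others and 4 splits as large.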

How the results depend on the processing

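The conclusions depend on the fit and on single replicates, the cause being tested only where said. For the diet counts in strain 13, SS, the strain counts on LS and HS, and the interaction (main 0, 37, 0, 81 and 5), single arrays gave 7, 125, 62, 186 and 46; forward arrays 15, 118, 70, 127 and 13; dye-swap arrays 3, 62, 51, 411 and 12; the ordinary per-probe test 1, 6, 1, 1 and 2; an unadjusted p of 0.01 29, 109, 101, 136 and 69. With 1 orientation alone, the dye effect of a probe does not cancel in the 4 comparisons. The forward and dye-swap counts may thus hold dye effects beside diet or strain differences. The single-array fit used a correlation of -0.018 between the arrays of an RNA pair. It thus counted the 2 arrays of a pair as separate values. Fitting a comparison alone gave 0 in SS, on HS and for the interaction, with fewer degrees of freedom. An adjusted p of 0.1 gave 99 in SS, 48 on LS, 136 on HS and 43 for the interaction. Closing the loop gave 58 in SS and 28 for the interaction. Equal spread gave 23 on LS, 13 on HS and 0 for the interaction; median centring left 4 for the interaction (3 higher, 1 lower). A ratio of at least 1.5 left 10 in SS (10 higher, 0 lower), 14 on HS (3 higher, 11 lower, against 49 and 32) and 1 for the interaction if the base is 2, and 24 in SS (18 higher, 6 lower) and 39 on HS (19 higher, 20 lower) if natural. Probes without missing values gave 23 for the interaction, and each kind of array alone (diet or strain) 0. Leaving out a replicate gave 0 to 57 in SS, 0 to 1 on LS, 0 to 19 on HS, 0 to 10 for the interaction, and 0 to 1 chromosome 13 genes where any gene was called. At an unadjusted p of 0.01, 2 chromosome 13 genes were called on LS, against 0. Without the array of conflicting labels SS gave 60. Added after seeing the data, the covariate gave 49 in SS, 1 on LS, 21 on HS, 44 for the interaction and 2 chromosome 13 genes (Fisher p = 0.106), and leaving out the sparse array gave 2 for the interaction. The cause was not tested for the other changes.

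The replicate block gave 31 in SS, 40 on HS, 8 for the interaction and 0 elsewhere. Same-numbered deviations correlated from -0.67 to 0.43, with 6 of 18 over 0.1, which falls short of every pair being over 0.1. The diet comparisons of both strains, which share no RNA, had 3 of 3 over it (0.15 to 0.25). A shared RNA would make some of these negative: of 12 pairs of comparisons that would share one, 8 had the sign this predicts, with all 3 only for the SS diet and HS strain comparisons (-0.67 to -0.29). In replicate 3 the channel names give a shared SS RNA on each diet. There the SS diet comparison correlated at -0.29 with the HS and 0.40 with the LS strain comparison, both of the predicted sign. Whether the numbers pair the samples in the other replicates stays open. Of the called named genes, 51 of 56 kept their call with median centring, 33 with equal spread, 42 with the block, 35 with the covariate, 21, 8 and 9 without replicate 1, 2 and 3, and 0 with the ordinary test or a comparison fitted alone. Vegfa turned to 0.14 in SS on dye-swap arrays and Igfbp5 to -0.02 on HS on forward arrays, where dye effects do not cancel. With an estimated correlation all 18 list shifts that camera had called at the preset correlation lost their call. With fry 10 lost and 3 gained one. For the transport list the estimated correlation was 0.0085, below the preset of 0.01. Its lost calls thus cannot be credited to a larger correlation between its genes. A limit on extreme values removed 0 probes and tests nothing.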

Other observations

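Of the steroid and vasoactive hormone list 0 of 12 genes passed in SS, and Nr3c1, the glucocorticoid receptor, had -0.15 ± 0.05 there (adjusted p = 0.226) and 0.13 ± 0.04 in strain 13. Hsd11b2, which inactivates glucocorticoid, had 0.27 ± 0.16 between strains on LS (adjusted p = 0.112). In the nitric oxide and eicosanoid list Hmox1, heme oxygenase 1, had 0.49 ± 0.21 in SS (adjusted p = 0.0617) and passed when adjusted over the list alone. Sord, of the polyol pathway, had -0.43 ± 0.04 in strain 13 (adjusted p = 0.417).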
